A study of Mus musculus with 4 samples.

How the data were processed

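Epithelial cells sorted for EpCAM from mouse mammary glands were profiled by single-cell RNA sequencing of transcript 3' ends with the 10x Genomics v3.1 kit. The 4 libraries cross 2 Esr1 genotypes (wild type and the Y541S mutant) with 2 treatments (vehicle and giredestrant, an oral antagonist and degrader of the estrogen receptor), and each combination has 1 library. The deposited matrices hold raw UMI counts per gene and cell barcode, and per the file headers they were made with Cell Ranger 6.0.1. The submitters' processing notes name the GRCm38 genome, and neither the annotation release nor the handling of intronic reads is stated. The deposited barcode and feature lists hold other text (cell barcodes, gene identifiers and symbols) in the order of the matrix columns and rows. All 4 matrices list the same 52636 genes, of which 52403 identifiers were found in the GRCm38 reference annotation used for gene coordinates and 233 were not. The lowest UMI count of a barcode was between 500 and 502 in every library.

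Barcodes were kept with 1000 or more UMIs, 500 or more genes and at most 15% mitochondrial UMIs, which left 25950 of 30062. Doublets were scored in each library with Scrublet in Scanpy 1.11.5. Its automatic threshold marked 0.028% of cells in the wild-type vehicle library, 0.561% in the wild-type giredestrant library, 3.20% in the Y541S vehicle library and 3.09% in the Y541S giredestrant library. Because the first of these shares is too low for a working call, and so after the automatic calls were seen, the highest-scoring cells of each library were removed up to an assumed rate of 0.8% per 1000 cells. This removed 401, 73, 417 and 595 cells in the same order, 1486 in all, and left 24464 cells. Median UMIs per barcode before filtering ranged from 5099 to 18690, a ratio of 3.67.

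Counts were scaled to 10000 per cell and log-transformed, and the 4 libraries were clustered together without integration, using 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). This gave 26 clusters. Clusters were named "-like" from marker lists fixed before the data were examined. A marker counted where its mean CPM was at least 4 times the median over clusters and at least 10% of cells held a UMI of it. A cluster took the class with the highest share of its markers counted, if that was at least 60% and at least 3 markers. It stayed unnamed if the median depth of its cells was under 1/3 of their library's and no marker of the class stood among its 10 leading genes. This scoring was set after the data had been seen and went through 3 versions. The first asked for 50% of the markers and named cluster 6 hormone-sensing-like. The second also left clusters with markers of another epithelial class unnamed, and it was dropped because it took the name from cluster 9, which holds most hormone-sensing-like cells of the wild-type giredestrant library. The third, used here, was chosen knowing that 60% leaves clusters 6 and 25 without a name and keeps cluster 9. The rule named 20 clusters and left 6 without a name (clusters 6, 8, 17, 19, 23 and 25).

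Counts were summed per library over the cells of a class and expressed as CPM. Ratios of 2 libraries carry exact 95% intervals from the conditional binomial distribution, levels carry exact Poisson intervals and shares of cells carry exact (Clopper-Pearson) binomial intervals. These cover counting error only. With 1 library per group there is no test between groups and no p-value, and the labels do not say how many animals a library holds. Gene lists were fixed before the data were examined. A list is described by the median log2 ratio of its members with 20 or more counts, by the number of members at least 1.5-fold higher or lower, by an interval from 1000 Poisson redraws, and by its percentile among 10000 random lists of genes matched on expression. The lists were estrogen response, progesterone response and paracrine factors, S phase, G2/M phase, milk protein and lactation, EGF family ligands and receptors, interferon response, unfolded protein response, immediate early and heat shock genes, cholesterol synthesis, MHC class II, p53 targets, NF-kB and acute phase, hypoxia and glycolysis, luminal keratins and adhesion, mesenchymal genes, and the markers of hormone-sensing, secretory, basal and keratinocyte cells. Where a gene had no counts in 1 library, the bound was taken at a floor of 3 counts over that library's sum.

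In hormone-sensing-like cells the median of all genes lay above 0 in the giredestrant comparisons, at a log2 ratio of 0.47 in wild type and 0.36 in Y541S, and at 0.12 for genotype under vehicle and 0.012 for genotype under giredestrant. Log2 ratios and list counts are therefore given relative to the median gene of their comparison and class, and are called relative log2 ratios. Among genes at 20 or more CPM the medians with giredestrant were lower, 0.301 in wild type and 0.238 in Y541S. Calls near 1.5-fold therefore depend on the genes that set the median. Levels in CPM are not shifted. The named genes were, by a rule fixed before the data were examined, Esr1, the members of the estrogen and progesterone lists, and the 8 genes higher and 8 genes lower with the largest ratio. The size of a ratio was the bound of its interval nearest to no difference, among genes at 50 or more CPM and with a UMI in at least 10% of cells in the higher library. Mitochondrial, ribosomal protein, predicted, haemoglobin, immunoglobulin, Xist, Y-linked and milk protein genes were left out of that ranking. For the difference between genotypes, the 6 genes with the largest difference of log2 ratios in each direction were named.

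Cycling cells were counted as cells with 3 or more of 10 G2/M genes after thinning each cell to 2000 UMIs, which left out 1046 shallower cells (153, 40, 80 and 773 in the order above). Co-detection of genes was counted on the same thinned cells. Own-library neighbours, 25% by chance, were counted among equal numbers of thinned cells of a class from each library, with 500 variable genes and 10 components. A cluster was taken as found mostly in the Y541S giredestrant library where its share there was at least 3 times that in each other library and at least 1%.

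The alternatives tried were a stricter cell filter (2000 UMIs, 10% mitochondrial UMIs), keeping the called doublets, resolution 1.5 and clustering each library separately. Another was clustering without 2850 genes, those at 20 or more CPM that differed at least 2-fold between any 2 libraries in sums of hormone-sensing-like cells. These sums left cluster 6 out, and genes that differed only in other cells stayed in. Further alternatives were edgeR 4.0.16 TMM factors in R 4.3.3, totals without mitochondrial, ribosomal protein and milk protein genes, means over cells, and a minimum of 200 counts per list member or none. The last were 2 or more G2/M genes, no thinning, and a threshold of 2 times the other libraries. A pair of alternatives was added after seeing the data: counting cluster 6 as hormone-sensing-like, and leaving out hormone-sensing-like clusters with a median mitochondrial share of 8% or more. Counts were also simulated from these sums as Poisson draws, the model these intervals assume, with no spread between cells or libraries. The 95% intervals held the true ratio for 95.1% of 13553 genes in the wild-type comparison. In the Y541S comparison they held it for 95.5% of 12620 genes. This coverage follows from the model, so it checks the calculation and not whether the intervals are wide enough for real cells and libraries. Of 100 genes set to differ 2-fold, the interval excluded no difference in the right direction for 94 and 98, and of 100 set to differ 4-fold, for all 100 in both. Of unchanged random lists, 5.0% and 5.5% fell outside the central 95% of matched lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.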

Results

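The libraries came from mammary glands of mice 6 months old that carried pellets of estradiol and progesterone and received vehicle or 30 mg/kg giredestrant by mouth each day for 4 days. Y541S denotes the replacement of a tyrosine of the estrogen receptor by serine. In the reference annotation (GRCm38), Esr1 lies on chromosome 10 from 4611593 to 5005614, and the codon of that tyrosine is TAT at positions 5001244 to 5001246, in the last exon. The count matrices carry no sequence, so the genotype is known from the labels alone. The wild-type vehicle library held 8114 barcodes and 98223195 UMIs. The wild-type giredestrant library held 3667 barcodes and 84215237 UMIs, the Y541S vehicle library 7812 barcodes and 132660456 UMIs, and the Y541S giredestrant library 10469 barcodes and 70781982 UMIs. After filtering, 6681, 2956, 6800 and 8027 cells remained in the same order, with median UMIs of 10753, 21631, 15016 and 6071. There were no replicates: each group is 1 library, so every difference below is between single libraries. The submitters' sample identifiers run in sequence for the first 3 libraries and not for the Y541S giredestrant library, and the labels give no batch.

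The cells fell into the epithelial classes of the mammary gland. Hormone-sensing-like luminal cells, which carry Esr1, Prlr and Foxa1, made up 9.64% (95% interval 8.94 to 10.4) of the wild-type vehicle library and 37.5% (35.7 to 39.3) of the wild-type giredestrant library. They made up 29.9% (28.8 to 31.0) of the Y541S vehicle library and 11.5% (10.8 to 12.2) of the Y541S giredestrant library. The last share rests on a naming threshold chosen after cluster 6 had been seen: the first version of the rule took cluster 6 as hormone-sensing-like, which gives 29.4%. Secretory-like luminal cells, which carry Elf5, Kit and Wfdc18, made up 10.3%, 21.1%, 22.9% and 18.8% in the same order. Basal-like cells, which carry Krt5, Krt14 and Acta2, made up 68.8%, 34.3%, 43.0% and 42.9%. Fibroblast-like cells were between 0.448% and 1.76% of a library, endothelial-like cells between 0.074% and 0.812%, and macrophage-like or dendritic-like cells between 0.199% and 0.838%. Unnamed clusters held 8.28%, 3.89%, 3.24% and 25.9%. Of these, cluster 8, shallow cells with basal markers, held 5.84%, 2.81%, 2.41% and 5.44% of the libraries. Cluster 23, with hormone-sensing markers, held 0.239%, 0.575%, 0.691% and none, and cluster 25, with secretory markers, held 0.120%, none, none and 0.324%. Cluster 17, with 2 of 7 hormone-sensing markers, held 177 cells, all of the Y541S giredestrant library (2.2%). Its median mitochondrial share was 8.65%, and Mgat4c and Unc5d, which also define cluster 10, were among its leading genes. Clusters 22 and 24, with 8.83% and 10.7%, had 6 of 7 markers and were named hormone-sensing-like. Counting cluster 17 would raise the 11.5%. The EpCAM sort and the recovery of cells after dissociation can set all of these shares. The labels also name the source as mature luminal cells, while basal-like cells were the most frequent class in 3 of 4 libraries, so whether a luminal gate was applied is uncertain.

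Different clusters held the hormone-sensing-like cells of different libraries. Cluster 3 held 90.7% of those in the wild-type vehicle library and 94.3% of those in the Y541S vehicle library. Cluster 9 held 89.5% of those in the wild-type giredestrant library and cluster 10 held 91.5% of those in the Y541S giredestrant library. With 1 library per group, a cluster mostly of 1 library may be that library and not a type. The sums compared below rest on 644, 1108, 2035 and 923 hormone-sensing-like cells. Secretory-like cells lay mostly in cluster 4 in the first 3 libraries (69.5%, 88.1% and 81.2%) and in cluster 7 in the Y541S giredestrant library (73.1%). Basal-like cells lay most often in clusters 1, 11, 5 and 0 (46.7%, 35.7%, 48.0% and 88.7%).

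**Figure D1:**
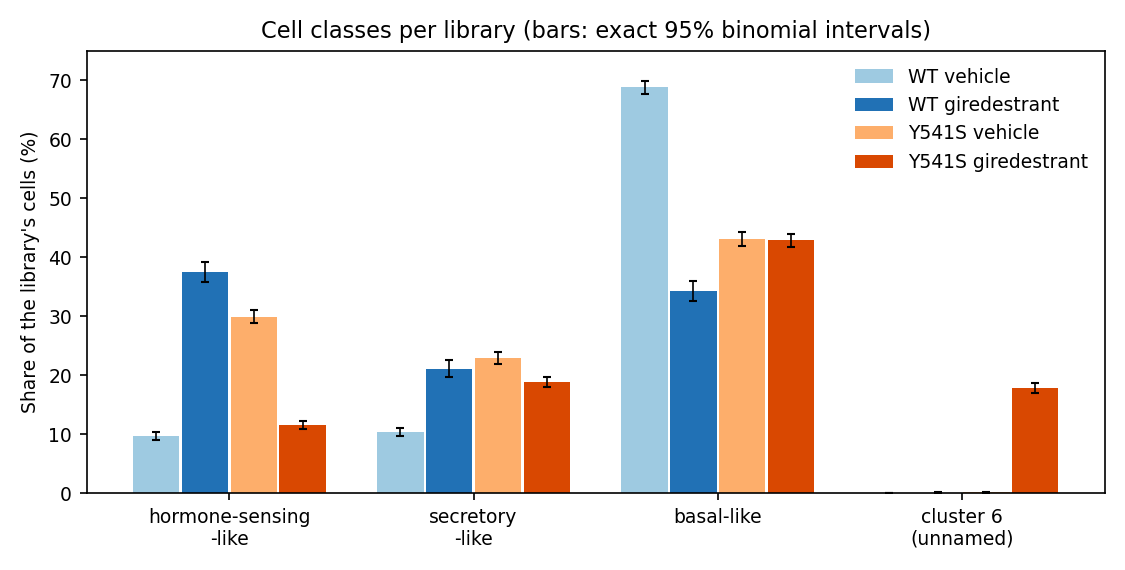
Bars give the share of each library's cells (%, vertical axis, from 0) in the hormone-sensing-like, secretory-like and basal-like classes and in unnamed cluster 6, for the 4 libraries, with exact 95% binomial intervals. Cluster 6 held 17.9% of the Y541S giredestrant library and at most 0.132% of any other.

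The comparison of giredestrant with vehicle in wild-type glands asks what the antagonist does where the receptor is intact. In hormone-sensing-like cells, some classical estrogen targets were far lower in the giredestrant library, while the estrogen response list as a whole was not set apart from matched lists. Greb1 (chromosome 12, 16670615 to 16800886), an estrogen-induced coactivator of the receptor, stood at 259 CPM with vehicle and 3.92 CPM with giredestrant, a relative log2 ratio of -6.51 (95% interval -6.74 to -6.29). Wisp2, an estrogen-induced secreted factor of the CCN family, stood at 86.3 and 1.59 CPM, and Pgr (chromosome 9, 8899833 to 8968611), which encodes the progesterone receptor, at 391 and 89.5 CPM (relative log2 ratio -2.59, -2.65 to -2.54). Stc2, a secreted glycoprotein, stood at 432 and 80.2 CPM and the lysosomal protease gene Ctsd at 1266 and 236 CPM. Esr1 itself was at 317 CPM with vehicle and 514 CPM with giredestrant.

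Of 19 measured members of the estrogen response list, 8 were at least 1.5-fold lower and 2 at least 1.5-fold higher, relative to the median gene. The lower members were Greb1, Wisp2, Stc2, Ctsd, Pgr, Xbp1 (136 and 113 CPM), Nrip1 (789 and 716 CPM) and Cxcl12, which was near 1 CPM. The higher members were Ccnd1, the cyclin of the G1 phase (61.4 and 168 CPM), and Celsr2 (15.1 and 39.6 CPM). The list's median relative log2 ratio was -0.25 (-0.37 to -0.14). Its unshifted median was 0.21, its unshifted mean was -0.71, and the median lay at percentile 41.4 of matched lists. Areg, which encodes the EGF receptor ligand amphiregulin, stood at 1722 and 2533 CPM. Scaling by TMM turned the direction of 5 of 46 named genes (Elovl5, Fhl2, Fkbp4, Myc and Rbbp8).

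Progesterone response genes were also lower in the wild-type giredestrant library. Of 10 members, 7 were lower and 1 was higher, with a median relative log2 ratio of -0.88 (-1.08 to -0.84). Fkbp5, a chaperone gene induced by steroid receptors, stood at 234 and 37.7 CPM and Tsc22d3 at 49.6 and 16.7 CPM. Tnfsf11, which encodes RANKL, a paracrine signal of the mammary gland, stood at 114 and 85.3 CPM. Per1, a clock gene, was the higher member (relative log2 ratio 1.24), and the Wnt ligand gene Wnt4 stood at 233 and 395 CPM.

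The 8 genes furthest above vehicle were Sbp, Upk3a, Kcnh1, Nckap5, Fxyd2, Ndst4, Fgb and Ror2. Sbp, a spermine-binding protein gene, had 6693 UMIs in the giredestrant library and none with vehicle, which makes it at least 1028-fold higher before the shift. Upk3a, a uroplakin gene, stood at 0.73 CPM with vehicle and 328 CPM with giredestrant, and the potassium channel gene Kcnh1 at 5.90 and 307 CPM. Nckap5 stood at 16.1 and 688 CPM, Fxyd2, a regulator of the sodium pump, at 9.13 and 371 CPM, and the fibrinogen beta chain gene Fgb at 8.46 and 292 CPM. Ndst4, an enzyme gene of heparan sulfate synthesis, stood at 1.20 and 54.1 CPM and Ror2, a Wnt receptor gene, had a relative log2 ratio of 4.56. Sbp, Upk3a and Fgb also led the list of genes that define cluster 9.

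The 8 genes furthest below vehicle were Klk1b1, Sprr2g, Klk1b21, Sftpd, Saa1, Klk1b27, Klk1 and Angptl7. Sftpd, which encodes the collectin surfactant protein D, stood at 275 CPM with vehicle and 0.29 CPM with giredestrant. The acute phase gene Saa1 stood at 171 and 0.19 CPM and Angptl7 at 70.1 and 0.22 CPM. Sprr2g, a small proline-rich protein gene, had 2037 UMIs with vehicle and 1 with giredestrant, a relative log2 ratio of -12.58 (-17.88 to -10.10). The kallikreins Klk1 (246 and 0.55 CPM), Klk1b1 (107 and 0.02 CPM, 1 UMI), Klk1b21 (119 and 0.05 CPM, 2 UMIs) and Klk1b27 (126 and 0.19 CPM) are close paralogs, so counts within the family may be shared among them.

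Several other groups differed in the same cells. Of 10 unfolded protein response genes, 9 were lower with giredestrant and none higher, with a median relative log2 ratio of -1.33 (-1.36 to -1.31). The chaperone gene Hspa5 stood at 624 and 372 CPM and Dnajb9 at 92.4 and 19.4 CPM. Of 8 NF-kB and acute phase genes, 5 were lower and 1 higher (median -2.14), with Lcn2, a siderophore-binding protein gene, at 1810 and 121 CPM. Interferon response genes were higher in 7 of 10 and lower in 2 (median 0.91), with Oasl2 at 7.31 and 42.4 CPM, and they were higher in secretory-like cells too (9 of 10, median 1.72). MHC class II genes were higher in 4 of 6 and lower in 1 (median 0.90), and S phase genes were higher in 5 of 12 and lower in 1 (median 0.45). Secretory markers were higher in 7 of 9 (median 2.40), with Wfdc18 at 50.4 and 350 CPM, and milk protein genes were higher in 4 of 7. Basal markers were lower in 8 of 10 (median -1.30) and also in secretory-like cells (7 of 8 lower, median -1.52), while basal-like cells were 68.8% of the vehicle library and 34.3% of the giredestrant library.

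In wild-type basal-like cells, immediate early and heat shock genes were higher in 9 of 11 and lower in 1 with giredestrant (median relative log2 ratio 0.68), with Fos at 690 and 1722 CPM. In hormone-sensing-like cells the same list had 3 higher and 1 lower (median 0.081). Greb1 in basal-like cells stood at 27.1 and 1.80 CPM. Krt15 was among the 8 genes furthest above vehicle there (301 and 939 CPM) and the protease inhibitor gene Slpi among the 8 furthest below (2953 and 685 CPM). In secretory-like cells the estrogen response list had 4 of 18 members lower and none higher (median -0.21).

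**Figure D2:**
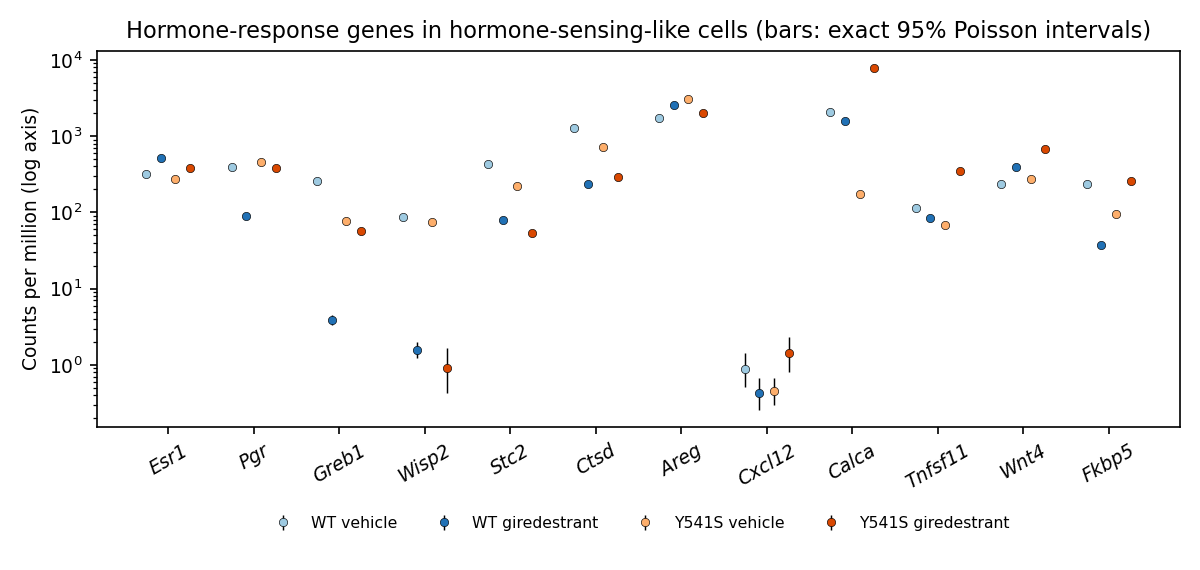
Points give levels in hormone-sensing-like cells (CPM, logarithmic vertical axis) of 12 hormone-related genes in the 4 libraries, with exact 95% Poisson intervals. Greb1 stood at 3.92 CPM in the wild-type giredestrant library and at 57.2 CPM or more in the other 3, while Wisp2 stood below 1.6 CPM in both giredestrant libraries.

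The comparison of giredestrant with vehicle in Y541S glands asks how cells with the mutant receptor respond. Part of the estrogen program was lower with giredestrant here too. Wisp2 stood at 75.3 CPM with vehicle and 0.90 CPM with giredestrant (relative log2 ratio -6.74, -7.80 to -5.86), Stc2 at 221 and 52.9 CPM, and Ctsd at 718 and 295 CPM. Pgr stood at 461 and 384 CPM (relative log2 ratio -0.62) and Greb1 at 78.3 and 57.2 CPM (relative log2 ratio -0.81). The lower Greb1 depends on leaving cluster 6 out: with it counted as hormone-sensing-like, an alternative chosen after seeing the data, Greb1 stood at 78.6 and 96.4 CPM (relative log2 ratio 0.051). Progesterone response genes were higher: Calca, which encodes calcitonin and its related peptide, stood at 175 CPM with vehicle and 7812 CPM with giredestrant.

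Of 22 measured estrogen response genes, 10 were lower and 5 higher relative to the median gene, with a median of -0.43 (-0.54 to -0.35). The unshifted median was -0.078 and lay at percentile 11.3 of matched lists. Besides those above, Areg (3029 and 1996 CPM), Myc (74.3 and 49.5 CPM), Slc9a3r1, Fkbp4 and Susd3 were lower. The higher members were Fhl2 (30.2 and 64.1 CPM) and Igfbp4, Mybl1, Cxcl12 and Pdzk1, which stood below 7 CPM. With cluster 6 counted, Fhl2 stood at 227 and Igfbp4 at 79.1 CPM in the giredestrant library. Esr1 stood at 276 and 378 CPM, and scaling by TMM turned the direction of Esr1, Elovl5, Per1 and Xbp1, 4 of 47 named genes.

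Of 10 progesterone response genes, 6 were higher and 2 lower, with a median relative log2 ratio of 0.81 (0.75 to 0.85), and the unshifted median exceeded that of all matched lists. Tnfsf11 stood at 69.4 and 350 CPM, Wnt4 at 275 and 677 CPM, Fkbp5 at 95.4 and 261 CPM and Zbtb16, a progesterone-induced transcription factor gene, at 95.6 and 196 CPM. Sgk1 (567 and 406 CPM) and Tsc22d3 (48.2 and 38.3 CPM) were the lower members. With cluster 6 counted, 5 were higher and 1 lower (median 0.56), with Calca at 3725, Tnfsf11 at 171 and Wnt4 at 419 CPM in the giredestrant library, and Wnt4 fell short of 1.5-fold (relative log2 ratio 0.36). Calca and Tnfsf11 were among the genes that define cluster 10.

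The other genes furthest above vehicle were Mgat4c, Cpe, Unc5d, Erbb4, Emb, Rhox5 and Tmprss6. Mgat4c, a glycosyltransferase gene, stood at 2.90 and 1236 CPM (relative log2 ratio 8.38, 8.15 to 8.62), and Cpe, which encodes a prohormone-processing carboxypeptidase, at 0.46 and 86.8 CPM. Unc5d, a netrin receptor gene, stood at 3.27 and 422 CPM, the receptor tyrosine kinase gene Erbb4 at 3.84 and 233 CPM and Emb at 2.44 and 151 CPM. The homeobox gene Rhox5 stood at 5.20 and 233 CPM and the membrane protease gene Tmprss6 at 11.9 and 484 CPM. Mgat4c, Unc5d, Rhox5 and Tmprss6 also define cluster 10.

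The genes furthest below vehicle were Dmbt1, Nrxn3, Wfdc3, Wisp2, Lcn2, Muc13, Lrg1 and Dcn. Dmbt1, a mucosal defence glycoprotein gene, had 4097 UMIs with vehicle and 1 with giredestrant, a relative log2 ratio of -10.07 (-15.37 to -7.59), or -5.43 with cluster 6 counted. The neurexin gene Nrxn3 stood at 1453 and 22.5 CPM, Lcn2 at 511 and 10.7 CPM, Lrg1 at 108 and 2.25 CPM and Wfdc3 at 115 and 1.53 CPM. Muc13, a transmembrane mucin gene, stood at 67.8 and 1.08 CPM, and Dcn, which encodes the matrix proteoglycan decorin and is also a fibroblast marker, at 138 and 3.88 CPM.

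Milk protein genes were higher in secretory-like cells of the Y541S giredestrant library. Of 11 members, 10 were higher and 1 lower, with a median relative log2 ratio of 2.76 (2.01 to 3.09). The casein genes Csn2 (10.3 and 3173 CPM), Csn1s1 (87.6 and 3561 CPM) and Csn1s2a (3.27 and 979 CPM) were among the higher members, while Csn3 stood at 1609 and 904 CPM. Csn1s1, Csn1s2a and Csn2 define cluster 7, which held 73.1% of these cells. Other classes of this library held Csn2 at background: after thinning, 3.86% of hormone-sensing-like, 4.96% of basal-like and 10.3% (3.89 to 21.2) of non-epithelial cells had a UMI of it, beside 62.7% of secretory-like cells, with median UMIs of 10637, 5468, 4459 and 6159. In secretory-like cells, 11 of 12 S phase genes (median -0.85) and 6 of 10 G2/M genes (median -0.77) were lower, and 1 G2/M gene was higher.

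Other groups in Y541S hormone-sensing-like cells also differed, and several depend on leaving cluster 6 out. NF-kB and acute phase genes were lower in 6 of 8 and higher in 1 (median -1.84), but with cluster 6 counted as hormone-sensing-like 4 were higher and 3 lower (median 0.32). With cluster 6 left out, hypoxia and glycolysis genes were lower in 6 of 9 (median -0.78), and luminal keratin and adhesion genes lower in 5 of 9 (median -0.91), with Krt8 at 4290 and 2193 CPM. Interferon response genes were higher in 4 of 9 and lower in 2 (median 0.55), and with cluster 6 counted higher in 1 and lower in 2 (median 0.066). The EGF family list had 5 of 10 members higher and 4 lower (median 0.13), and with cluster 6 counted 6 higher and 3 lower (median 1.83), with the receptor gene Egfr at 1.05 and 42.0 CPM. Cluster 10, most of these cells, had Egfr at 12.4 and Krt14 at 51.0 CPM and the cycling cluster 18, over all libraries, 99.1 and 462 CPM. Few cells may therefore carry much of these class values. The cluster values are means over cells and the class values come from summed counts of this library, so the measures are unlike. Mesenchymal genes were higher in 6 of 7 (median 1.84) at low levels, with Fn1 at 4.47 and 34.2 CPM and Vim at 0.55 and 1.89 CPM. Basal markers were higher in 8 of 9 (median 2.15), with Krt14 at 5.19 and 121 CPM, and free RNA is not excluded there, since 10.5% of thinned hormone-sensing-like and 10.1% of secretory-like cells of the giredestrant library had a UMI of Krt14, at median UMIs of 10637 and 6159. In secretory-like cells they were higher in 7 of 10 and lower in 2 (median 2.15). Mir6236, Cmss1 and Erdr1 were higher with giredestrant in each epithelial class: Mir6236 stood at 37.3 and 814 CPM in hormone-sensing-like cells and 53.2 and 1548 CPM in secretory-like cells.

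The comparison of the genotypes under vehicle asks what the mutation does with hormone pellets alone. G2/M genes were higher and progesterone response genes lower in the Y541S library. In hormone-sensing-like cells, G2/M genes were higher in 8 of 10 (median relative log2 ratio 0.68, 0.59 to 0.81) and S phase genes in 3 of 12 (median 0.36). The first of these lists exceeded all matched lists. Of 10 progesterone response genes, 6 were lower and 1 higher (median -0.63, -0.71 to -0.45), with Calca at 2099 CPM in wild type and 175 CPM in Y541S and Fkbp5 at 234 and 95.4 CPM. Of 20 estrogen response genes, 4 were higher and 4 lower (median 0.040): Areg (1722 and 3029 CPM), Myc (34.0 and 74.3 CPM), Ccnd1 (61.4 and 101 CPM) and the scarce Susd3 were higher, and Greb1 (259 and 78.3 CPM), Stc2 (432 and 221 CPM), Ctsd (1266 and 718 CPM) and the scarce Cxcl12 were lower.

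The genes furthest above wild type were Krt15, Nrxn3, Nckap5, Nlrp4e, Dgki, Tph1, Fam107b and Erdr1. The keratin gene Krt15 stood at 9.19 CPM in wild type and 112 CPM in Y541S, Nrxn3 at 250 and 1453 CPM, Nckap5 had a relative log2 ratio of 2.47 and Nlrp4e stood at 13.4 and 59.1 CPM. The diacylglycerol kinase gene Dgki stood at 17.2 and 64.1 CPM, Tph1, which encodes an enzyme of serotonin synthesis, at 92.3 and 303 CPM, Fam107b at 84.4 and 267 CPM and Erdr1 at 23.9 and 77.1 CPM. The genes furthest below were Klk1b27, Klk1b21, Klk1, Aldh3a1, Megf11, Calca, Gnb4 and Bpifc. Klk1 stood at 246 and 13.2 CPM and its paralogs Klk1b27 at 126 and 2.14 CPM and Klk1b21 at 119 and 2.81 CPM. The aldehyde dehydrogenase gene Aldh3a1 stood at 74.1 and 5.04 CPM, the G protein subunit gene Gnb4 at 80.6 and 7.71 CPM and Bpifc at 51.3 and 5.65 CPM, and Megf11 had a relative log2 ratio of -3.97.

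Basal markers were lower in 10 of 10 in the Y541S hormone-sensing-like cells (median -1.48), while basal-like cells were 68.8% of the wild-type and 43.0% of the Y541S vehicle library. Cholesterol synthesis genes were lower in 4 of 12 and higher in none (median -0.39). Interferon response genes were lower in 5 of 9 in hormone-sensing-like cells (median -0.64) and higher in 6 of 9 and lower in 1 in secretory-like cells (median 0.83). MHC class II genes in basal-like cells were lower in 4 of 7 (median -1.45). Scaling by TMM turned the direction of 2 of 46 named genes (Nrip1 and Xbp1).

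The comparison of the genotypes under giredestrant sets the mutant beside wild type in the presence of the antagonist. Greb1 stood at 3.92 CPM in wild type and 57.2 CPM in Y541S (relative log2 ratio 3.86), Pgr at 89.5 and 384 CPM (2.09, 2.03 to 2.14), and Fkbp5 at 37.7 and 261 CPM. Of 10 progesterone response genes, 8 were higher in Y541S and none lower, with a median of 1.03 (0.78 to 1.14). Of 20 estrogen response genes, 6 were higher and 3 lower (median 0.12, 0.040 to 0.17). The higher members were Greb1, Pgr, Fhl2, Igfbp4, Mybl1 and Cxcl12, the last 3 below 7 CPM in both libraries, and the lower members were Stc2 (80.2 and 52.9 CPM), Slc9a3r1 (128 and 77.1 CPM) and Wisp2 (1.59 and 0.90 CPM). With cluster 6 counted, 10 of 21 were higher and 5 lower (median 0.28), and Stc2 was higher in Y541S at 117 CPM (relative log2 ratio 0.65). Scaling by TMM turned 2 of 47 named genes (Myc and Nrip1) and took the unshifted list median from 0.13 to -0.062.

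The genes furthest above wild type were Mgat4c, Unc5d, Penk, Rhox5, Pnmt, Spock1, Frmd5 and Slpi. Mgat4c stood at 0.12 CPM in wild type and 1236 CPM in Y541S. Unc5d had 1 UMI in wild type and 4682 in Y541S (relative log2 ratio 14.09, 11.61 to 19.39), and Penk, which encodes the precursor of enkephalins, had 1 and 4178 (13.92, 11.45 to 19.23). Rhox5 stood at 0.46 and 233 CPM, Pnmt, which encodes the enzyme that makes adrenaline, at 0.14 and 94.6 CPM, the proteoglycan gene Spock1 at 0.10 and 70.0 CPM, Frmd5 at 3.41 and 721 CPM and Slpi at 4.09 and 822 CPM. The genes furthest below were Dmbt1, Sbp, Fgb, Fgg, Nrxn3, Ly6d, Ccbe1 and Ido1. Dmbt1 stood at 52.1 CPM in wild type and had 1 UMI in Y541S (relative log2 ratio -9.19, -14.49 to -6.71, or -4.55 with cluster 6 counted), and Sbp stood at 161 and 1.17 CPM. The fibrinogen chain genes Fgb and Fgg stood at 292 and 6.22 CPM and at 381 and 9.74 CPM, Nrxn3 at 780.0 and 22.5 CPM, Ly6d at 828 and 29.9 CPM (110 CPM with cluster 6 counted), Ccbe1 at 206 and 7.03 CPM and Ido1, which encodes a tryptophan-degrading enzyme, at 117 and 4.06 CPM.

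In the same cells, p53 targets were higher in Y541S in 5 of 8 and lower in none (median 1.05), with the cell cycle inhibitor gene Cdkn1a at 109 and 254 CPM. Unfolded protein response genes were higher in 8 of 10 (median 0.79), and in 4 of 10 with cluster 6 counted (median 0.49). Interferon response genes were lower in 8 of 10 (median -1.45), MHC class II genes in 4 of 6 (median -1.09), immediate early and heat shock genes in 10 of 11 (median -0.94, and 5 of 11 with median -0.49 with cluster 6 counted), and hormone-sensing markers in 5 of 7 (median -0.84), with Prlr at 3988 and 1834 CPM. Secretory markers were lower in 8 of 9 (median -2.74), and keratinocyte markers were higher in 1 of 4 (median 0.14).

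The difference between the 2 giredestrant comparisons asks whether the genotypes respond alike. It was not tested, since each rests on a single pair of libraries. In hormone-sensing-like cells the estrogen response list differed by a median of 0.21 relative to the median gene (Y541S minus wild type), with 6 of 19 genes at least 1.5-fold higher and 5 lower, and the progesterone list by 1.42, with 8 of 10 higher and 1 lower. The unfolded protein response list differed by 0.95, with 10 of 10 higher (0.74 and 6 of 10 with cluster 6 counted), and S phase genes by -0.98, with 8 of 12 lower. The single genes furthest apart were Mgat4c, Unc5d, Spock1, Pnmt, Penk and Slpi, lower with giredestrant in wild type and higher in Y541S, and Dmbt1, Nrxn3, Fgg, Fgb, Ido1 and Ndst4 the other way. Spock1, for example, stood at 18.6 and 0.10 CPM in wild type and 2.23 and 70.0 CPM in Y541S, and Slpi at 710.0 and 4.09 CPM and at 136 and 822 CPM. Mgat4c, Unc5d and Penk were scarce in both wild-type libraries, at most 7.99 CPM. Ndst4 was close to level in Y541S at 2.84 and 2.52 CPM.

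The series title concerns a cell population of the mutant under receptor antagonism, and a cluster of that kind was present. Cluster 6 held 1435 cells of the Y541S giredestrant library, 17.9%, 9 cells of the Y541S vehicle library, 0.132% (0.061 to 0.251), and no cell of either wild-type library, which allows shares of up to 0.0449% with vehicle and 0.102% with giredestrant if 3 cells are taken as the limit, and up to 0.055% and 0.125% by the exact interval. Clustering was also done without the genes that differed 2-fold between libraries in hormone-sensing-like cells. The matching cluster then held 18.5% of the Y541S giredestrant library and at most 0.191% of another. Within that library, cluster 6 held Esr1 at 384 CPM, beside 378 CPM in hormone-sensing-like and 18.9 CPM in basal-like cells. Prlr stood at 409, 1834 and 9.23 CPM in the same order, Foxa1 at 71.1, 109 and 1.77 CPM and Areg at 3100, 1996 and 24.9 CPM. It had 4 of 7 hormone-sensing markers and 3 basal markers counted, short of the share needed for a name under the final rule.

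Cluster 6 also held part of the basal profile. Krt14 stood at 1727 CPM, beside 121 CPM in hormone-sensing-like and 3268 CPM in basal-like cells, and Trp63, the basal transcription factor gene, at 166, 20.7 and 184 CPM. Other basal keratins lay further below basal-like cells, with Krt5 at 90.0, 11.5 and 639 CPM and Krt17 at 378, 46.6 and 2290 CPM. The contractile genes of myoepithelial cells were near the level of luminal cells: Acta2 stood at 32.9, 28.0 and 6684 CPM and Myh11 at 9.82, 9.11 and 1160 CPM. Its leading genes included the stress keratin genes Krt6a and Krt16, Epgn, and Il33, the gene of an alarmin cytokine. Egfr stood at 641, 42.0 and 269 CPM. Of 10 progesterone response genes, 7 were at least 1.5-fold lower than in hormone-sensing-like cells and 3 higher. Calca stood at 136 CPM beside 7812 CPM in hormone-sensing-like cells and Tnfsf11 at 13.4 beside 350 CPM. The median UMI count was 7747 in cluster 6, 10637 in hormone-sensing-like and 5468 in basal-like cells, and 0.370% (0.120 to 0.862) of cluster 6's thinned cells were cycling. Clusters 12, 13 and 18 had G2/M genes among their leading genes, and cluster 18 held 71 cells of this library. The clustering itself can therefore set the cycling share of cluster 6 low.

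Without clustering, Krt6a at 2 or more UMIs together with Krt14 was found in 11.4% (10.7 to 12.1) of thinned cells of the Y541S giredestrant library, in 0.260% and 0.034% of the wild-type vehicle and giredestrant libraries and in 0.060% of the Y541S vehicle library. Krt6a is a leading gene of cluster 6, so this count is not separate support for it. Krt6a at 2 or more UMIs, with or without Krt14, was found in 16.5%, 1.93%, 0.377% and 2.59% in the same order. Prlr and Krt14 without Acta2 were found together in 7.02%, 0.260%, 0.617% and 0.268%. Prlr, Krt14 and Acta2 together, which free RNA or doublets can give, were found in 1.45%, 0.306%, 0.377% and 0.491%. Clusters found mostly in the Y541S giredestrant library (0, 6, 7, 10, 16 and 17) held 84.2% (83.3 to 84.9) of its cells, so basal-like and secretory-like cells also lay apart by library. With clustering done without the genes that differed 2-fold in hormone-sensing-like cells, such clusters held 55.6%. Genes that differed only in other classes stayed in.

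**Figure D3:**
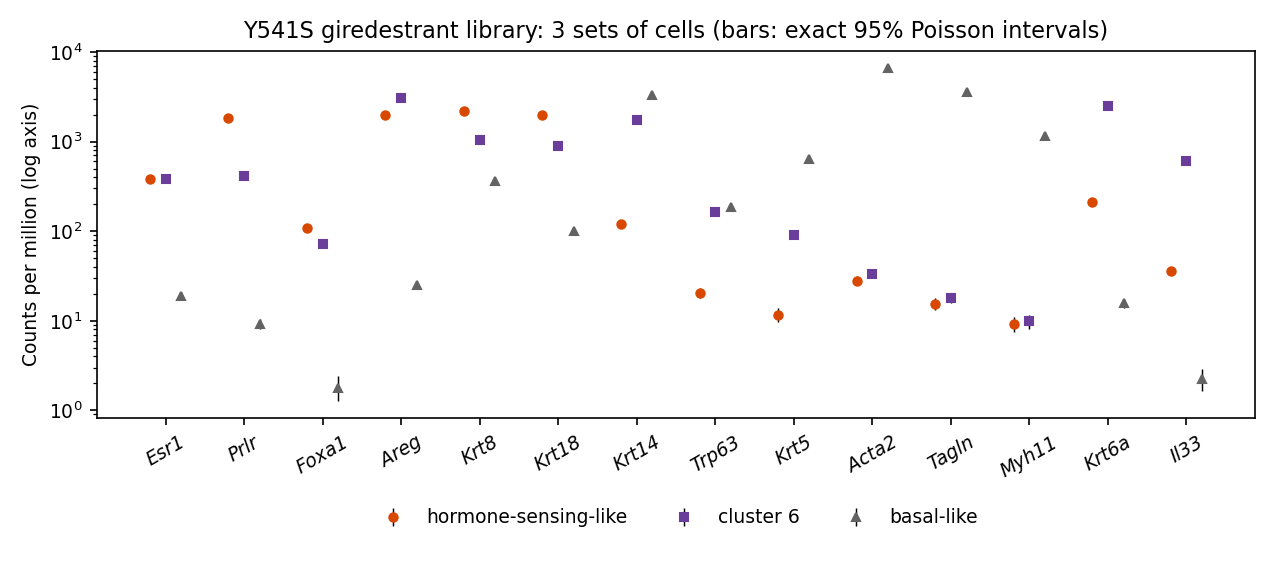
Points give levels (CPM, logarithmic vertical axis) of 14 genes in hormone-sensing-like cells, cluster 6 and basal-like cells of the Y541S giredestrant library, with exact 95% Poisson intervals. In cluster 6, Trp63 stood at 89.8%, Krt14 at 52.8% and Krt5 at 14.1% of the level in basal-like cells, while Acta2, Tagln and Myh11 lay near the hormone-sensing-like level.

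Cycling cells were most frequent in the Y541S vehicle library. After thinning to equal depth, 2.53% (2.16 to 2.94) of wild-type vehicle, 3.05% (2.46 to 3.74) of wild-type giredestrant, 4.64% (4.15 to 5.17) of Y541S vehicle and 3.61% (3.19 to 4.07) of Y541S giredestrant cells were cycling. Without thinning the shares were 5.76%, 10.5%, 10.9% and 5.62%. In secretory-like cells the thinned shares were 6.96%, 6.49%, 10.9% and 7.95%, in hormone-sensing-like cells 2.19%, 2.90%, 3.60% and 6.25%, and in basal-like cells 1.53%, 1.39%, 2.44% and 3.05%. The last hormone-sensing-like share rests on leaving cluster 6 out. With cluster 6 counted it was 2.69% (2.06 to 3.45), below the Y541S vehicle library, with the G2/M list at 190 and Mki67 at 33.0 CPM. Summed levels in hormone-sensing-like cells were 119, 237, 169 and 141 CPM for the S phase list and 143, 260, 255 and 365 CPM for the G2/M list. Mki67 stood at 11.4, 30.8, 19.3 and 64.3 CPM.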

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

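All tests weighed in this part were chosen only after the result was seen. The share of hormone-sensing-like cells was higher with giredestrant in wild type (log2 ratio 1.96) and lower in Y541S (-1.38), a difference of -3.34 that stood out because the genotypes went opposite ways. Among hormone-sensing-like and secretory-like cells alone, the wild-type shares were closer, 48.2% with vehicle and 64.0% with giredestrant. In Y541S they were 56.6% and 37.9%. Part of the wild-type ratio thus goes with the lower basal-like share of its giredestrant library. The opposite directions depend on a choice made after cluster 6 had been seen. The first naming rule counted cluster 6 as hormone-sensing-like, which gives 29.4% in the Y541S giredestrant library beside 30.1% with vehicle, a log2 ratio of -0.033. The difference is then -1.99, with the wild-type ratio as before. None of the differences between genotypes in this part was tested, as each rests on 4 single libraries.

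In hormone-sensing-like cells, relative log2 ratios with giredestrant also went opposite ways in the genotypes, by at least 1.5-fold each way for a pair of lists and at least 2-fold each way for 12 genes. The genes searched were Esr1, the members of the estrogen and progesterone lists and the genes named for the difference between genotypes. All of the 12 but Fkbp5 and Cxcl12 had been named for their large difference in these same data. That choice favours opposite directions, so the count is no separate support, and the share over all genes was not computed. The progesterone list stood at -0.88 in wild type and 0.81 in Y541S (difference 1.69). The basal marker list stood at -1.30 and 2.15 (difference 3.45), where free RNA from basal cells is not excluded. With cluster 6 counted, the progesterone list stood at 0.56 and Fkbp5 at 0.75 in Y541S, short of these sizes, while Id2 (-1.30 and 1.03) and Ndst4 (5.03 and -1.41) passed, for 13 genes in all. Genes lower in wild type and higher in Y541S were Mgat4c (difference 14.90), Unc5d (14.62), Spock1 (12.68), Pnmt (11.62), Penk (10.98), Slpi (10.15), Fkbp5 (4.20) and Cxcl12 (2.79), the last with at most 1.44 CPM in any library. In wild type, Mgat4c stood at only 7.99 CPM with vehicle and 0.12 CPM with giredestrant. Unc5d stood there at 4.33 and 0.02 CPM and Penk at 1.83 and 0.02 CPM. The wild-type part of these differences thus rests on very few UMIs. Genes higher in wild type and lower in Y541S were Nrxn3 (difference -7.54), Fgg (-6.40), Fgb (-6.36) and Ido1 (-5.72).

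The estrogen targets Greb1 and Pgr were far lower with giredestrant in wild type and little lower in Y541S, while Wisp2, Stc2 and Ctsd were lower in both, but with cluster 6 counted Greb1 was not lower in Y541S (relative log2 ratio 0.051) and Pgr stood at -1.05. The 118 genes at least 4-fold lower in wild type had a median log2 ratio of -1.357 in Y541S, where 70 were at least 2-fold lower and 7 at least 2-fold higher. This argues against an inactive dose in the Y541S animals only if no effect of the library within hormone-sensing-like cells lowered the same genes. They were chosen by their level with vehicle, so any other departure from the vehicle state could lower them. A shift of the whole library, alike in each class, is argued against, because that median lay -1.408 from the lower of the medians of secretory-like (0.12) and basal-like cells (0.051). Neither value was recomputed with cluster 6 counted. Retained activity of the mutant receptor may contribute as a hypothesis, but the estrogen response list, with members going both ways, gave a median difference of only 0.102 before the shift, which decides nothing. An effect of the single Y541S giredestrant library within hormone-sensing-like cells stays open, since genotype, treatment and library cannot be told apart there.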

How the results depend on the processing

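A pair of the alternatives used here was chosen after seeing the data (counting cluster 6 as hormone-sensing-like, and leaving out clusters rich in mitochondrial UMIs). The share of hormone-sensing-like cells stayed within its counting interval in 18 of 24 alternative values. The others were 35.3% in the wild-type giredestrant library with each library clustered separately and 31.3% in the Y541S vehicle library with doublets kept. In the Y541S giredestrant library they were 12.7% with the stricter filter, 12.4% with doublets kept and 13.2% with clustering without the 2850 genes differing in hormone-sensing-like cells. There it was also 29.4% with cluster 6 counted in, which follows from its construction and was the outcome of the first naming rule. With it the Y541S libraries differ little (30.1% with vehicle), so the lower share with giredestrant is not settled.

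The unshifted median of the estrogen response list stayed within its counting interval in 49 of 60 alternative values, moved in 7 and turned sign in 4. In wild type it was 0.21, with doublets kept 0.057, without a count minimum 0.33, and with TMM -0.17. In Y541S it was -0.078, with TMM -0.59, with totals without mitochondrial, ribosomal protein and milk genes -0.19, with 200 or more counts per member -0.26, and with cluster 6 counted in -0.19. For genotype under giredestrant it was 0.13, with doublets kept 0.24, with TMM -0.062 and with the minimum of 200 counts -0.036. The difference between genotypes was 0.10, and -0.020 with TMM. TMM moved the log2 ratios of all genes alike, by -0.39, -0.51, -0.07 and -0.19 in the 4 comparisons, which accounts for its sign changes. For the other values the cause was not tested. A shift of all genes leaves the medians relative to the median gene as they were, -0.25 in wild type and 0.21 for the difference, so only the unshifted sign depends on the scaling there. For genotype under giredestrant the sign is not settled, as the minimum of 200 counts turned it too.

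Relative log2 ratios of Esr1, the list members and the genes named by rank were also recomputed with cluster 6 counted as hormone-sensing-like, in the 2 comparisons that use the Y541S giredestrant library. Of 94 values, 22 stayed within their counting interval, 68 moved and 4 turned sign with an interval that excluded 0. In Y541S with giredestrant, Ccnd1 went from 0.18 to -0.48 and Greb1 from -0.81 to 0.051. For genotype under giredestrant, Areg went from -0.36 to 0.134 and Stc2 from -0.61 to 0.654, while Celsr2, whose interval held 0, went from -0.15 to 0.017. These follow from the levels of the added cells, and why the cells have them was not tested.

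The same step was taken for the relative medians of the gene lists, also after seeing the data. Of 40 values, 15 stayed within their interval, 21 moved and 4 turned sign with an interval that excluded 0. In Y541S with giredestrant, NF-kB and acute phase genes turned from -1.84 to 0.32 and cholesterol synthesis genes from 0.31 to -0.042. For genotype under giredestrant, NF-kB and acute phase genes turned from -0.37 to 1.879 and G2/M genes from 0.23 to -0.665. The values that moved in Y541S were 0.558 (progesterone response), -0.728 (S phase), -1.107 (G2/M), 1.834 (EGF family), 0.066 (interferon), -0.524 (unfolded protein), -0.46 (immediate early and heat shock), -0.586 (hypoxia), -0.787 (luminal keratins), -1.336 (hormone-sensing markers) and 0.264 (keratinocyte markers, from -0.18 with an interval that held 0). For genotype under giredestrant they were 0.276 (estrogen response), 1.215 (progesterone response), 1.477 (EGF family), -1.954 (interferon), 0.487 (unfolded protein), -0.491 (immediate early and heat shock), -0.795 (luminal keratins), -1.296 (hormone-sensing markers), 1.949 (basal markers) and -2.306 (secretory markers). The cause was not tested beyond the levels of the added cells.

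The share of cycling cells stayed within its interval under the cell filter, doublet and resolution alternatives. With 2 G2/M genes it was 3.63%, 4.66%, 6.49% and 5.06%, in the same order of libraries, and without thinning 5.76%, 10.5%, 10.9% and 5.62%, which changes the order. Clusters found mostly in the Y541S giredestrant library held 88.7% of it with the stricter filter and 91.5% at resolution 1.5, against 84.2%. They held 55.6% with clustering without the 2850 genes differing in hormone-sensing-like cells. Named genes higher in the first library numbered 22, 26, 24 and 28, and 17, 22, 22 and 26 with TMM.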

Other observations

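The tests of cluster 6 and the test of depth in secretory-like cells were chosen only after the results were seen, and the tests of own-library neighbours in basal-like and non-epithelial cells were written before, without a number of cells. Cluster 19, with 139 cells in the wild-type vehicle library and 15 in the wild-type giredestrant library, had the hair follicle keratins Krt25, Krt71 and Krt28 among its leading genes and stayed unnamed. In basal-like cells, the agouti gene a stood at 1671, 2269, 7365 and 1028 CPM in the wild-type vehicle, wild-type giredestrant, Y541S vehicle and Y541S giredestrant libraries. Slpi in these cells stood at 2953, 685, 1441 and 140 CPM, and Lingo2 at 135, 12.3, 10.4 and 181 CPM. Greb1 in basal-like cells stood at 27.1, 1.80, 19.6 and 20.6 CPM, while Pgr stood at 11.4, 13.4, 11.3 and 12.2 CPM.

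Secretory-like cells of the Y541S giredestrant library had the mucin gene Muc4 at 433 CPM, against 107, 40.0 and 45.3 CPM in the wild-type vehicle, wild-type giredestrant and Y541S vehicle libraries. Pdk4, a regulator of pyruvate oxidation, stood at 160, 26.9, 32.7 and 232 CPM in these cells, and the cystatin gene Cst3 at 243, 455, 220.0 and 30.5 CPM. MHC class II genes in basal-like cells were higher with giredestrant in 6 of 7 in Y541S (median 0.91) and lower in 3 of 7 in wild type (median -0.36), with Cd74 at 65.8, 57.4, 45.1 and 160 CPM. Macrophage-like or dendritic-like cells were 0.838%, 0.643%, 0.221% and 0.199% of the libraries.

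Cluster 6 combined transcripts of hormone-sensing cells with Krt14, Trp63 and Krt6a. Doublets of hormone-sensing and basal cells are argued against. Relative to Krt14, 6 contractile genes stood at a median of 0.010 of their ratio in basal-like cells. That value also goes against free RNA of basal-like cells as the source of Krt14. The lower of the Krt14 and Krt6a ratios to luminal cells was 11.772. It decides nothing on free RNA, because Krt6a is a leading gene of the cluster, which may have gathered cells by it. Dissociation stress stays open. The immediate early and heat shock list differed from hormone-sensing-like cells by a median log2 ratio of -0.067, low enough to go against it by the written prediction. A further condition, absent from that prediction, was that members do not go both ways. With 1 of 11 members at least 1.5-fold higher and 2 lower, the median was therefore taken to decide nothing. The cluster may be a state of cells related to hormone-sensing cells, which stays a hypothesis. An effect of the single library, in which 1435 of its 1444 cells lie, is not excluded.

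Cells of the Y541S giredestrant library lay apart from the others in clustering, but in hormone-sensing-like cells this is not particular to it, since at 500 cells per library 94.02% of neighbours came from the own library, and 92.16% in the wild-type giredestrant library. After thinning to 2000 UMIs, its basal-like cells had -0.24 percentage points more neighbours of their own library than the mean of the other 3 libraries at 30 cells per library and 14.96 at 500, so lower depth is left open for them, while in secretory-like cells an excess of 38.39 points at equal depth argues against depth as the whole cause. A library effect on every cell type stays open: non-epithelial cells differed from basal-like cells by 5.14 points, which decides nothing because basal-like cells had no excess at that number, and at 15 cells per library fibroblast-like cells had an excess of 28.59 points and basal-like cells -1.67. Removing Mir6236, Cmss1, Erdr1 and mitochondrial, ribosomal and predicted genes lowered the excess at 500 cells to 7.91 points in basal-like cells, but 28.88 points remained in secretory-like cells. This took out 28504 of the 52636 genes, so the fall cannot be put to a few transcripts of technical origin, and their part stays open. The labels give no batch, so a separate preparation of this library cannot be told apart from its genotype and treatment.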
